A study of Mus musculus with 13 samples.

How the data were processed

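RNA was sequenced from epididymal adipose tissue and from prostate tumours of TRAMP mice, a transgenic line that develops prostate cancer. Per the labels, the mice were C57BL/6, 30 to 35 weeks old and on a regular diet, and either carried an unrecombined floxed p62 gene (wild type) or lacked p62 in adipocytes. p62 is the autophagy receptor and signalling scaffold encoded by Sqstm1. There were 3 wild-type and 3 knockout adipose libraries, and 4 wild-type and 3 knockout tumour libraries, 13 in all. Per the labels, tissue was frozen, polyadenylated RNA was selected, libraries were made with a directional kit, and single-end reads of 75 bases were read on a NextSeq 500. Groups and replicate numbers were taken from the labels. The labels do not say that each library came from a separate mouse, so the p-values measure only the spread between these libraries, which can be partly technical.

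The submitters' processing notes name STAR, DESeq2 and the mouse build mm10, without versions or roles. The read counter and the annotation are not given in the sources used here. The deposited tumour table holds raw counts per gene, as its values show: whole numbers with a different total in each library. The deposited adipose table names no unit either. Its values are not whole, sum to 1.11e+06 to 2.11e+06 per library and are very high for genes of under 100 bases, which neither counts, CPM nor TPM would give, so the deposited values were read as FPKM. The median of the non-zero adipose values lay between 8.35 and 8.48 in every library, so the authors' values carry a further scaling between libraries. Changes of total RNA cannot be seen in either table. The tables are in different units, and each effect was computed within its own table.

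There are 23360 entries for adipose tissue and 24421 for tumours, with 22615 gene symbols in both. Spreadsheet conversion had turned 27 adipose and 13 tumour symbols into dates; these stayed in the tests and are not named. A symbol already present was repeated by 4 entries in each table. Gene positions were looked up by symbol in GENCODE release M21, of the same mouse assembly, which held 12752 of the 13617 adipose genes tested and 14567 of the 15117 tumour genes tested. The directional kit marks strand, but no source used here says whether counting used it, so overlapping and antisense genes are uncertain, and so are reads shared between near-identical genes such as the haemoglobin and seminal vesicle secretory families.

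Adipose FPKM were tested as log2(FPKM + 1) with limma 3.58.1 (trend) in R 4.3.3, for genes with a mean of at least 1 FPKM over the 6 libraries. Fold changes of adipose tissue are therefore on the log2(FPKM + 1) scale, which understates the change of low genes. The planned test had been edgeR for counts and limma for normalized values, and limma was used because the adipose table does not hold counts. Tumour counts were tested with edgeR 4.0.16 (TMM normalization, filterByExpr with a minimum count of 10, quasi-likelihood test), and with DESeq2 1.42.0 and limma voom as alternatives. The difference between the adipose and tumour effects was tested with limma (trend) on the 12390 genes tested in both tables, with 4 groups in 1 fit. That fit used log2(FPKM + 1) and log2(CPM + 1), so its tumour medians over these genes differ from those of edgeR. Camera and list scores of tumours alone used log2 CPM with a prior count of 2. All p-values are two-sided, adjusted by Benjamini-Hochberg, and called at an adjusted p under 0.05.

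Before the data were examined, 29 gene lists were fixed: oxidative phosphorylation, TCA cycle, fatty acid oxidation, fatty acid and triglyceride synthesis, lipolysis and lipid droplet, cholesterol synthesis, branched-chain amino acid catabolism, glycolysis, thermogenic adipocyte, mature white adipocyte, NRF2 targets, autophagy and lysosome, amino acid response and serine synthesis, cell cycle, interferon response, inflammatory and secreted signals, mesenchymal transition and invasion, macrophage, T and NK cell, B cell and plasma cell, endothelial, fibroblast and matrix, mesothelial, smooth and skeletal muscle, epididymis and seminal vesicle, prostate luminal and androgen response, prostate basal, neuroendocrine, and erythroid and blood. Lists with at least 5 measured genes were tested with camera (limma), with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, were alternatives. Within each list, genes were also counted with p-values adjusted over the list alone. List scores are means over the genes of a list, in each library, of the log2 value minus the mean of the wild-type libraries of that tissue, and groups of scores were compared by an exact two-sided permutation test, adjusted over 28 lists per tissue.

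The rule for naming genes was fixed before the data were examined. It takes Sqstm1; per tissue and direction, up to 10 called genes with the largest change, no overlap between the groups and a mean of at least 50 counts or 1 FPKM, or the 5 smallest p-values where fewer than 5 were called; up to 4 genes of smallest p from each list described; and a set tied to the question of the study (Spp1, Cd44, Cpt1a, Fabp4, Adipoq, Lep, Pparg, Ppargc1a, Ucp1, Fasn, Acaca, Scd1, Dgat2, Pnpla2, Nfe2l2, Mki67 and Vim). For the tissue difference it takes called genes only, and there were none. Gene models without a symbol were counted and not named. Some genes that the rule takes are not reported here.

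Replicate numbers were checked for pairing by the correlation, over genes, of the deviations of same-numbered libraries from their group means. In tumours these correlations were 0.18, 0.11 and 0.27, all over 0.1, so the numbers were treated as pairs there, and blocked values are given where they change a call. In adipose tissue they were -0.05, 0.15 and 0.15, and the numbers were not treated as pairs. The labels name no pairs, so pairing in tumours is an assumption. Differently numbered libraries of opposite groups reached 0.18 in adipose tissue and 0.05 in tumours. The main tests used no pairs. The labels also do not say whether same-numbered adipose and tumour libraries came from 1 mouse. Between tissues the correlations of same-numbered libraries were 0.03, 0.02 and -0.05 in wild type and -0.16, 0.14 and -0.03 in knockout. Differently numbered ones reached 0.12 in wild type and 0.26 in knockout. The test of the tissue difference treated all 13 libraries as separate, so mice shared between tissues would affect its p-values.

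The tumour libraries held 1.78e+07 to 3.25e+07 counts. In the adipose table the number of reads is not given, but the lowest values move in steps whose size depends on depth. The most frequent ratio of these steps, over 1044 to 1600 genes, gave depths relative to knockout 1. They were 2.75 for knockout 2 (140 of 1600 genes at that ratio) and 0.84 to 1.11 for the other 4 libraries. A further scaling between libraries would change these estimates. No counts were rebuilt from these steps.

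The tests were tried on simulated data with 200 changed genes, all drawn from genes above the median level. Recovery among lower genes was not tried. The noise of each gene was set from a fitted spread already drawn towards that of other genes, and genes were drawn independently. Recovery and false shares may therefore differ in the real libraries. Of genes changed 2-fold, 4-fold and 8-fold, edgeR recovered 2.99%, 58.2% and 92.4% in simulated tumour counts, with 6 false calls among 108 (5.56%). DESeq2 recovered 13.4%, 92.5% and 98.5%, with 67 false calls among 203 (33.0%), far above the 5% aimed at. Limma recovered 14.9%, 88.1% and 90.9% in simulated adipose values, with 12 false calls among 141 (8.51%), and 0%, 33.3% and 79.0% for the simulated tissue difference, with 0 false calls among 70. Camera found a list raised by 1 on the log2 scale in simulated adipose values (adjusted p = 5.94e-27) and none of the other lists. The simulated genes were drawn independently, so this does not test camera where genes of a list move together. In the real adipose values the estimated correlation reached 0.86, for cell cycle genes. Alternatives covered the normalization, the filter, the tool, the threshold, the pseudocount, the libraries in the fit, the replicate block and leaving out each library in turn.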

Results

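The series compared mice lacking p62 in adipocytes with wild-type mice, in 2 tissues of TRAMP animals: epididymal fat, whose adipocytes were to lose the gene by design, and the prostate tumour, which was not. Its title sets metabolism in fat against metabolism in the tumour, so each tissue was compared between genotypes and the effects of the tissues were then compared with each other. The adipose libraries (3 labelled wild type, 3 labelled knockout) were deposited as FPKM-like values and the tumour libraries (4 labelled wild type, 3 labelled knockout) as raw counts. Total counts were 1.78e+07, 2.36e+07, 1.78e+07 and 1.97e+07 in wild-type tumours 1 to 4, and 2.01e+07, 3.25e+07 and 2.26e+07 in knockout tumours 1 to 3.

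Sqstm1, the gene of p62, was examined first in each library. It lies on chromosome 11 from 50199366 to 50210827 (mm10, minus strand) and is protein coding. In adipose tissue it stood at 73.6, 1.77 and 84.3 FPKM in the libraries labelled wild type 1 to 3, and at 4.53, 54.5 and 2.58 FPKM in those labelled knockout 1 to 3. The libraries numbered 2 thus went against their labels: the library labelled wild type 2 had the lowest value of the 6, and the library labelled knockout 2 had more than 10 times the values of the other libraries labelled knockout. With the labels as deposited the log2 fold change was -1.33 (SE 1.503, n = 3 and 3, limma adjusted p = 0.698). Tumours were not designed to lose the gene, yet Sqstm1 counted 3243, 135, 2358 and 3165 in the tumours labelled wild type 1 to 4 and 178, 6053 and 461 in those labelled knockout 1 to 3. In CPM this is 173, 5.65, 167 and 151 against 8.97, 176 and 19.5. Again the libraries numbered 2 went against the rest of their group (log2 fold change -0.87, SE 1.21, n = 4 and 3, edgeR adjusted p = 0.812). All directions below follow the labels as deposited, "knockout" and "wild type" mean libraries so labelled, and the main changes without the libraries numbered 2 are given beside the results.

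**Figure D1:**
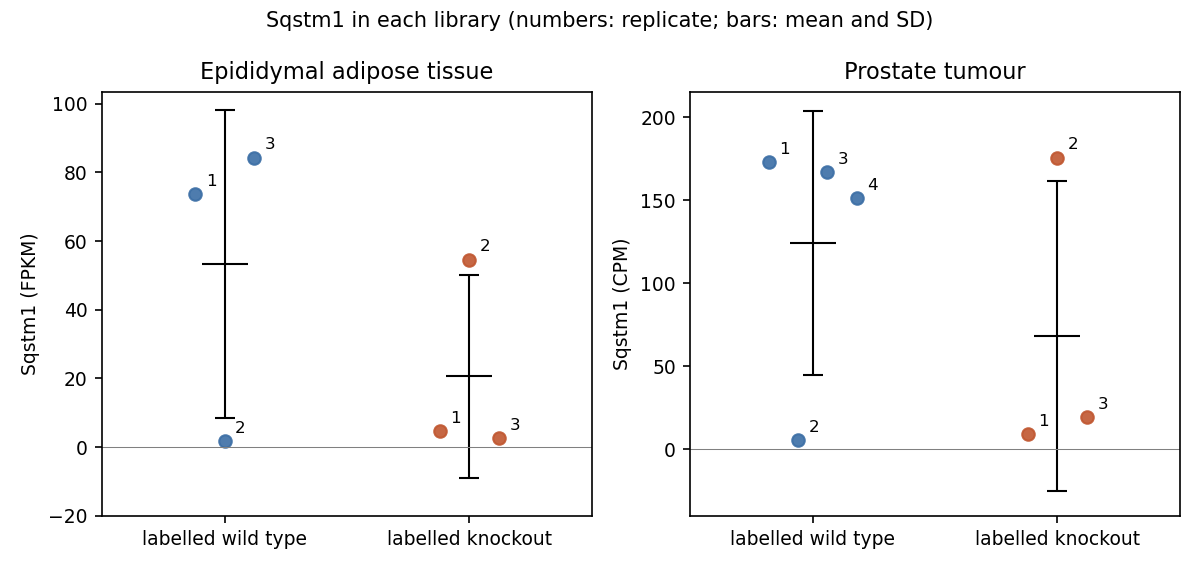
Sqstm1 in each library, with adipose values in FPKM and tumour values in CPM, by labelled group; each point is 1 library with its replicate number. In both tissues the library labelled wild type 2 (1.77 FPKM and 5.65 CPM) lies among the low values and the library labelled knockout 2 (54.5 FPKM and 176 CPM) among the high ones.

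In epididymal fat, genes of fatty acid and triglyceride synthesis were lower in the libraries labelled knockout, with 25 of 27 measured genes lower and a median log2 fold change of -1.75. Fasn, the fatty acid synthase, stood at 447 ± 253 FPKM in wild type and 32.9 ± 23.0 in knockout (SD, n = 3 each; log2 fold change -3.85, SE 0.76). Dgat2, which makes triglycerides, stood at 751 ± 42.5 and 108 ± 108 FPKM (log2 fold change -3.31, SE 0.69). Genes of mature adipocytes, cholesterol synthesis, the TCA cycle and oxidative phosphorylation were lower as well, by medians of -1.07, -0.72, -0.58 and -0.47. Macrophage markers were higher in all 17 measured genes (median 1.34), and so were cell cycle genes in all 29 (median 1.22). Single genes did not pass the test with the exception of Snord61, and these group results rest on camera with its preset correlation: of the 15 lists it called, 0 were called with an estimated correlation (adjusted p = 0.487 for each) and 0 by fry.

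Of 13617 genes tested in adipose tissue, limma called 1 (0 higher, 1 lower), between 2 and 4 when any 1 library was left out (2 without wild type 3, 4 without knockout 1), 20 with a stricter filter and 48 with all 13 libraries in 1 fit. The gene, Snord61 (chromosome X, 57391449 to 57391519, minus strand), is a small nucleolar RNA of 71 bases, shorter than the reads of 75 bases. High FPKM of so short a gene may rest on few reads, whose number is not given. Snord61 was listed at 1698, 1063 and 1235 FPKM in the wild-type libraries and at 0 in all 3 knockout libraries (limma adjusted p = 4.89e-06). It is 1 of 199 tested genes with under 300 bases, and 0 genes were called without these. At an unadjusted p under 0.05 there were 2045 genes (937 higher and 1108 lower) where 681 would be expected by chance. This count was 1266 without wild type 3, 1306 without wild type 1, 1329 without knockout 1 and 2878 without knockout 3. The group ranges did not overlap in 2886 genes (21.2%, against 10% by chance for 3 against 3).

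The lipid synthesis list gave the smallest camera p (adjusted p = 2.16e-13 with the preset correlation; adjusted p = 0.487 with an estimated correlation). When adjusted over the list alone 19 of its 27 genes were lower, and 0 over all genes tested. The count was 11 without knockout 2, and 12 without wild type 1, without wild type 3 or without knockout 1. Acss2, which makes acetyl-CoA from acetate, stood at 69.0 ± 21.95 FPKM in wild type and 9.47 ± 3.18 in knockout (log2 fold change -2.75, SE 0.33, limma adjusted p = 0.127). Me1, malic enzyme, had a log2 fold change of -3.21 (SE 0.43), Elovl6, a fatty acid elongase, one of -2.83 (SE 0.41), and Scd2, a desaturase, one of -3.17 (SE 0.46), all at limma adjusted p = 0.127. Fasn (adjusted p = 0.171), Acaca (-2.36, adjusted p = 0.184), Dgat2 (adjusted p = 0.173) and Scd1 (-2.42, adjusted p = 0.279) did not pass over all genes either.

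Among mature white adipocyte genes 21 of 23 were lower (camera adjusted p = 2.18e-07; adjusted p = 0.487 with an estimated correlation). Adjusted over the list alone 5 were lower, between 1 (without wild type 1, wild type 3 or knockout 1) and 10 (without knockout 3), with 2 without wild type 2. Pnpla3 had a log2 fold change of -4.25 (SE 0.63), the hormone gene Retn one of -2.03, Npr3 one of -2.27 and Tusc5 one of -1.20. None of these passed over all genes, nor did other adipocyte genes: Adipoq, for adiponectin, had -0.55 (limma adjusted p = 0.548), Fabp4 0.12 (0.940), Lep -1.30 (0.444) and Pparg, the master regulator of adipocyte differentiation, -1.32 (0.264). The thermogenic list was lower in 9 of 11 genes (median -0.87, camera adjusted p = 0.00351; adjusted p = 0.487 with an estimated correlation), 2 of them when adjusted over the list alone, 1 without wild type 2, knockout 1 or knockout 2 and 3 without knockout 3. It included Adrb3, the beta-3 adrenergic receptor (-2.90, SE 0.41), and Cox8b (-2.77). Ppargc1a had -0.77 (adjusted p = 0.442) and Ucp1 was below the minimum for testing, at a mean of 0.520 FPKM in wild type and 0.697 in knockout.

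Mitochondrial lists followed the same direction. In the TCA cycle list 23 of 24 genes were lower (camera adjusted p = 1.31e-07). Of these 7 passed when adjusted over the list alone, between 2 (without wild type 1 or wild type 3) and 11 (without wild type 2), with 4 without knockout 1 or knockout 2. The mitochondrial pyruvate carrier genes Mpc1 and Mpc2 had -1.88 and -1.60, Pdhb -1.60 and Idh3a -1.43. In oxidative phosphorylation 65 of 76 genes were lower (camera adjusted p = 1.29e-08), 6 when adjusted over the list alone, 0 without wild type 1 and 1 without both libraries numbered 2. Examples were Ndufa3 (-1.48), Cox7a2 (-1.70), Uqcrq (-1.58) and Cox6a1 (-1.70). Cholesterol synthesis was lower in 21 of 22 genes (camera adjusted p = 1.31e-07). Of these 5 passed when adjusted over the list alone, from 1 (without wild type 1 or knockout 1) to 10 (without knockout 2), with 2 without wild type 3 and 3 without knockout 3. Sc5d had -2.70, Acat2 -1.20, Nsdhl -1.51 and Idi1 -1.25. Fatty acid oxidation was lower in 20 of 29 genes (median -0.35, camera adjusted p = 0.00803), including Decr1 (-1.22) and Hadh (-0.89), while Cpt1a, its rate-limiting carnitine transferase, had 0.58 (SE 0.34, limma adjusted p = 0.455). Each of these 4 lists had adjusted p = 0.487 with an estimated correlation.

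Several smaller lists passed camera and were less stable. Lipolysis and lipid droplet genes had a median of -0.57 (adjusted p = 0.0238, and 0.193 without knockout 1 and 0.0634 without both libraries numbered 2), with Adrb3, Bscl2 (-1.29) and Cav1 (-1.78) lower and Plin2, a lipid droplet coat protein, higher (2.06) when adjusted over the list alone. These 4 became 1 without wild type 1, wild type 3 or knockout 1, 2 without knockout 2 and 8 without knockout 3; Pnpla2 had -0.67. Branched-chain amino acid catabolism had a median of -0.54 (adjusted p = 6.53e-04, and 0.0548 without knockout 2). Glycolysis had a median of -0.35 (adjusted p = 0.0482, and 0.107 without wild type 1, 0.0511 without wild type 2 and 0.306 without knockout 3). Autophagy and lysosome had one of 0.28 (adjusted p = 0.0334, and 0.124, 0.137, 0.164 and 0.1004 without wild type 1, wild type 3, knockout 1 and knockout 3). These 4 lists also had adjusted p = 0.487 with an estimated correlation. Eno1, with -2.17, may share reads with near-identical pseudogenes, which was not examined, and is uncertain.

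Macrophage markers were higher in 17 of 17 genes (camera adjusted p = 3.26e-07; adjusted p = 0.487 with an estimated correlation), with 0 passing when adjusted over the list alone, 12 without wild type 2 and 4 without knockout 2. Cd14 had 1.51 (SE 0.40), the hyaluronan receptor gene Lyve1 1.28, Csf1r 1.17 and Clec10a 1.71. Inflammatory and secreted signals were higher in 17 of 22 genes (median 0.90, camera adjusted p = 0.00314; adjusted p = 0.487 with an estimated correlation), with 0 passing when adjusted over the list alone, 5 without wild type 2 and 2 without knockout 3. Within it Spp1, for osteopontin, stood at 1052, 99.9 and 18.3 FPKM in knockout 1 to 3 and at 5.12, 18.3 and 6.39 in wild type 1 to 3 (log2 fold change 3.73, SE 1.30, limma adjusted p = 0.266). Gpnmb had 3.89, Trem2 2.68 and Tgfb1 0.88. The scores of this list overlapped, with wild type 2 (1.16) above knockout 3 (0.43). Markers of the other cell types did not pass camera: T and NK cells -0.13 (adjusted p = 0.941), B cells -0.07 (0.992), endothelium 0.12 (0.0994), fibroblasts and matrix -0.12 (0.939), mesothelium -0.23 (0.739) and muscle -0.12 (0.402), as list medians. Only 6 of 20 T and NK cell, 5 of 18 B cell and 9 of 18 muscle genes were measured, so these lists cover their cells only in part. The endothelial list passed without wild type 1, knockout 1 or knockout 2 (adjusted p = 0.0370, 0.00464 and 0.0455). So did the mesothelial and muscle lists without wild type 2 (0.0144 and 0.0499) and without both libraries numbered 2 (0.0295 and 0.00696).

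Cell cycle genes were higher in 29 of 29 (camera adjusted p = 1.29e-08; adjusted p = 0.487 with an estimated correlation), with 0 passing when adjusted over the list alone and 27 without knockout 3. The list score was 1.83 and 1.91 in knockout 1 and 2 and -0.11 in knockout 3, against 0.04, 0.51 and -0.55 in wild type. Aurka had 1.73, Mcm3 1.30, Nusap1 1.57, Mcm7 0.94 and Mki67 1.82 (limma adjusted p = 0.424). Neuroendocrine genes were higher in 17 of 17 (median 1.25, camera adjusted p = 4.46e-05; adjusted p = 0.487 with an estimated correlation). Scores were 0.95, 2.41 and 0.31 in knockout 1 to 3, with a wild-type range from -0.04 to 0.04. These are low transcripts such as Stmn2 (1.93 ± 1.14 and 11.2 ± 7.32 FPKM) and Chgb (0.0210 ± 0.0364 and 9.82 ± 14.3 FPKM; both SD, n = 3 each).

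The remaining adipose lists did not pass: NRF2 targets (median -0.28, adjusted p = 0.421), amino acid response and serine synthesis (0.02, 0.542), interferon response (0.15, 0.835), mesenchymal transition and invasion (0.23, 0.0670), prostate luminal (-0.34, 0.198), prostate basal (0.08, 0.577) and erythroid and blood (1.68, 0.0670). Without single libraries 3 of them passed: the mesenchymal list without wild type 1, wild type 2 or knockout 1 (0.0155, 0.0434 and 0.0164), the prostate luminal list without wild type 2 (0.0434) and the erythroid list without wild type 2, wild type 3 or knockout 2 (0.0335, 0.0104 and 0.0239) or without both libraries numbered 2 (0.00547). The epididymis and seminal vesicle list had 1 measured gene, Lcn5 (wild-type mean 3.27 FPKM, listed at 0 in knockout), and was not tested. Among NRF2 targets 3 genes were higher and 3 lower when adjusted over the list alone, 6 in all against 2 without wild type 1, wild type 3 or knockout 1 and 4 without knockout 2 or knockout 3. They included Hmox1, haem oxygenase (2.28, limma adjusted p = 0.161), and the pentose phosphate enzyme genes Pgd (-0.89) and Tkt (-1.39); Nfe2l2, which encodes NRF2, had 0.13 (0.812). The serine synthesis genes Psat1 and Phgdh had -1.47 and -1.49, in a list with 12 genes higher and 10 lower. Of these 1 higher and 5 lower passed when adjusted over the list alone. Further genes with the smallest p-values were Thbs2 (2.98, limma adjusted p = 0.137), Hlx (1.54) and Syce2 (1.52), and Tmem45b (-2.14), Tlcd1 (-1.74) and Snhg3 (-1.67, all 3 at 0.127); none passed. Cd44 had 1.18 (0.423) and Vim 0.70 (0.487).

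For list scores an exact permutation test of 3 against 3 libraries cannot give a p below 0.1, so in adipose tissue the libraries themselves cannot pass 0.05. Without both libraries numbered 2, limma called 5 genes and 17 lists, and 14 genes of the lipid synthesis list passed when adjusted over the list alone.

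**Figure D2:**
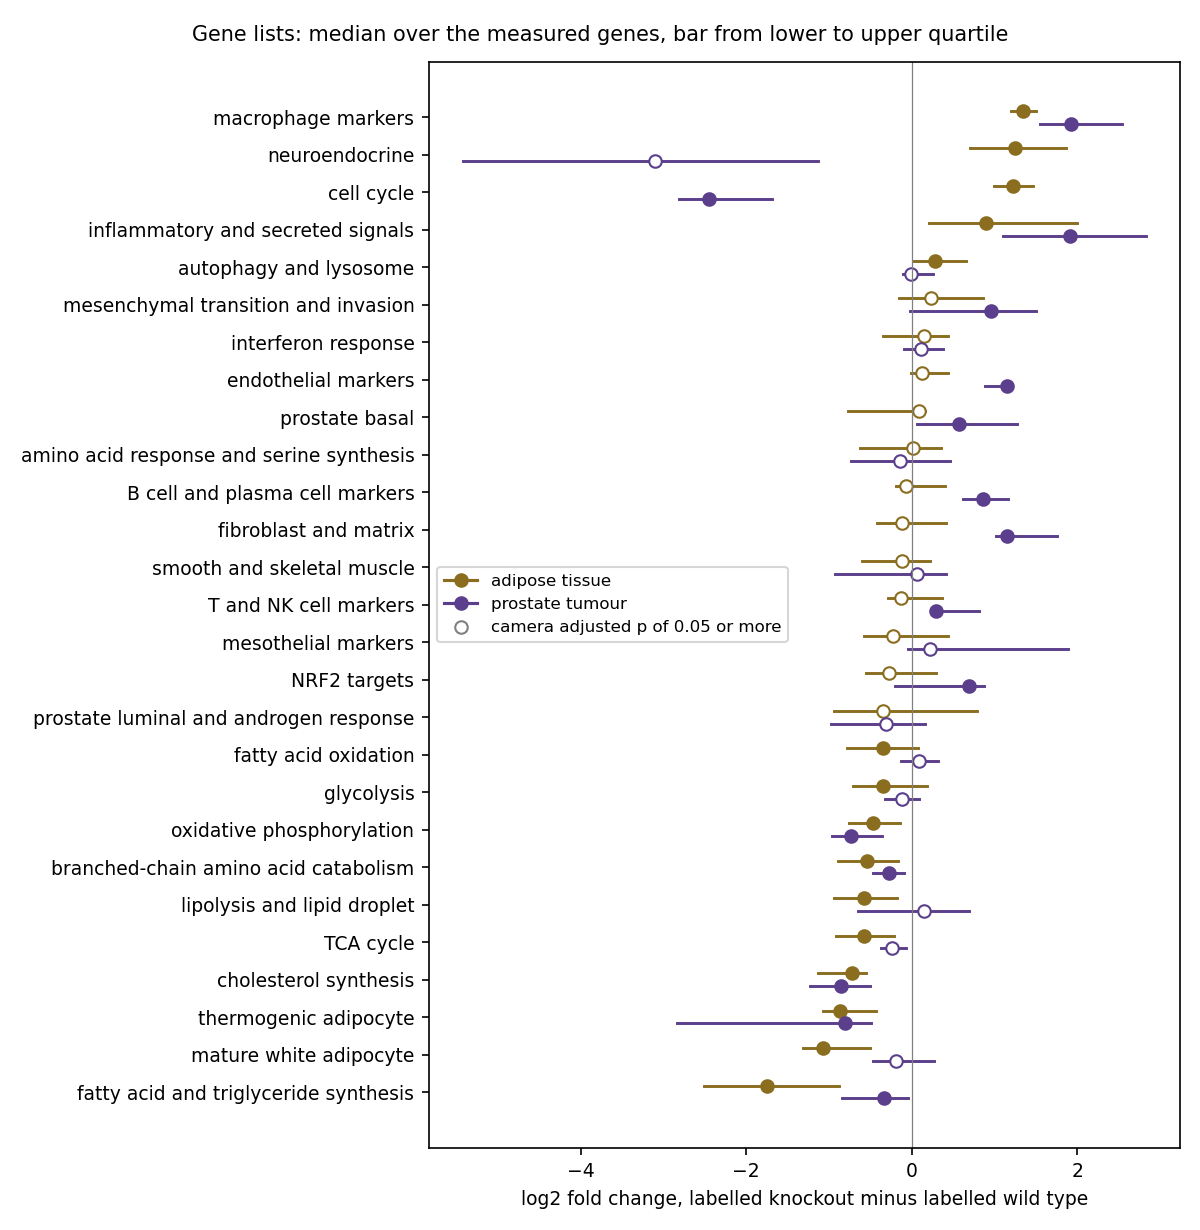
Median log2 fold change of each gene list tested in both tissues, knockout minus wild type as labelled, on the log2(FPKM + 1) scale for adipose tissue and the log2 count scale for tumours; bars run from the lower to the upper quartile over genes and open points have a camera adjusted p of 0.05 or more. Cell cycle genes lie at 1.22 in adipose tissue and -2.45 in tumours, and macrophage markers at 1.34 and 1.92.

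In prostate tumours, cell cycle genes were lower in mice labelled as lacking adipocyte p62, in all 30 measured genes and by a median log2 fold change of -2.45. Mki67, a marker of dividing cells, stood at 508 ± 379 CPM in wild type (SD, n = 4) and 59.2 ± 41.5 in knockout (SD, n = 3; log2 fold change -3.10, SE 0.77). Cholesterol synthesis genes were lower in 23 of 24 (median -0.85). Macrophage markers were higher in 18 of 18 genes (median 1.92) and inflammatory and secreted signals in 23 of 24 (median 1.91), as were endothelial and fibroblast genes. No single gene passed edgeR's test over all genes, and the groups rest on camera with its preset correlation and on tests within each list. Of the 15 lists it called, 0 were called with an estimated correlation (smallest adjusted p = 0.109) and 1 by fry.

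Of 15117 genes tested in tumours, edgeR called 0 (smallest adjusted p = 0.193) and voom 0, while DESeq2 called 780 (358 higher and 422 lower). DESeq2 had a false share of 33.0% in simulated counts with 200 changed genes. That share depends on how many genes change, so the false share among the 780 is not known. At an unadjusted p under 0.05 edgeR had 1879 genes (933 higher and 946 lower; 756 expected by chance), voom 1610 and DESeq2 2226. The edgeR count was 1176 without knockout 2 and 1000 without both libraries numbered 2. The DESeq2 count and its balance depended on single libraries: 457 without knockout 1 (207 higher, 250 lower), 473 without knockout 2 (127 and 346), 572 without knockout 3 (352 and 220) and 402 without both libraries numbered 2 (74 and 328). Group ranges did not overlap in 2077 genes (13.7%, against 5.71% by chance).

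In the cell cycle list (camera adjusted p = 4.39e-34; adjusted p = 0.222 with an estimated correlation) all 30 genes were lower when adjusted over the list alone, 0 with edgeR over all genes and 27 with DESeq2 over all genes. Nusap1 had -2.41 (SE 0.46), the kinase gene Ttk -2.97, Cenpf, of the kinetochore, -3.58 and Cdk1 -2.12, all at edgeR adjusted p = 0.193. The genes of smallest p in the whole table included more of this kind, Kif20b (-2.18), Ckap2 (-2.01), Knstrn (-2.57) and Cdca2 (-2.47), with the histone gene H2afx at -1.58 (edgeR adjusted p = 0.193 for each; DESeq2 adjusted p from 5.77e-06 to 2.50e-05). List scores were -2.37, -1.45 and -3.36 in knockout 1 to 3 and 0.75, -0.27, -0.20 and -0.28 in wild type 1 to 4. An exact permutation test gave p = 0.0286, the smallest possible for 4 against 3 with the pairs ignored (adjusted p = 0.133 over 28 lists). Wild type 1 stood apart with the highest cell cycle score and with neuroendocrine genes at a score of 3.98, against -1.76 to -0.67 in the other 6 tumours; Chgb, for chromogranin B, reached 276 CPM there.

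Cholesterol synthesis genes were lower with camera (adjusted p = 3.86e-12; adjusted p = 0.109 with an estimated correlation) and were the only list that fry called (adjusted p = 0.0266). Adjusted over the list alone 9 of 24 were lower, 6 without knockout 1 or knockout 3, 15 without wild type 3 and 4 without both libraries numbered 2; DESeq2 called 8 over all genes. Fdps stood at 43.1 ± 8.96 CPM in wild type and 16.1 ± 1.86 in knockout (log2 fold change -1.42, SE 0.25), Insig1 had -1.32, Cyp51 -1.35 and Sqle, the squalene epoxidase, -1.69 (edgeR adjusted p = 0.193 for all 4). Fatty acid and triglyceride synthesis was lower in 21 of 28 genes (median -0.34, camera adjusted p = 0.00164; 0.0588 without knockout 3; adjusted p = 0.278 with an estimated correlation). Adjusted over the list alone 1 gene passed, and 0 when any library but wild type 1 was left out. Dgat2 had -1.29 (edgeR adjusted p = 0.193, DESeq2 8.64e-04), Fasn -0.84 (0.210, DESeq2 0.0104), Acaca -0.88 (0.307) and Scd1 -0.86 (0.567).

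Oxidative phosphorylation was lower in 73 of 75 genes (median -0.74, camera adjusted p = 1.34e-07; adjusted p = 0.643 with an estimated correlation), with 0 passing when adjusted over the list alone; examples were Cycs (-1.25) and Cox7a2 (-1.04). Its score was 1.11 in wild type 3 and between -0.68 and -0.24 in all other tumours, and wild type 3 also had a TMM factor of 0.794, against 0.986 to 1.07 elsewhere. Branched-chain amino acid catabolism was lower (median -0.28, camera adjusted p = 0.0199; 0.0569 without wild type 2, 0.403 without wild type 3 and 0.131 without knockout 2, and 0.234 without both libraries numbered 2; adjusted p = 0.644 with an estimated correlation). So was the thermogenic list (median -0.81, camera adjusted p = 0.00645; 0.0756 without wild type 3; adjusted p = 0.301 with an estimated correlation), Ucp1 with -3.38 (edgeR adjusted p = 0.537). Wild type 3 carried these genes as well, with the highest thermogenic score (1.08), Ucp1 at 75.6 CPM against 1.39, 1.67 and 14.3 in the other wild-type tumours, Cox8b at 59.6 CPM and Cidea at 36.7 CPM. The TCA cycle (median -0.24, adjusted p = 0.0985) and fatty acid oxidation (0.09, 0.0735) did not pass; the latter passed without wild type 3 or knockout 2 (4.84e-04 and 0.00996) and without both libraries numbered 2 (0.0261). In it Cpt1a stood at 93.8 ± 38.5 CPM in wild type and 196 ± 63.0 in knockout, with no overlap (log2 fold change 1.06, SE 0.37, edgeR adjusted p = 0.304), and Acadl had 1.03 (0.307).

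Macrophage markers were higher with camera (adjusted p = 3.86e-12; adjusted p = 0.278 with an estimated correlation) and in 16 of 18 genes when adjusted over the list alone, 5 without knockout 2. Lyve1 had 2.64 (SE 0.55), Cd14 2.13, the integrin gene Itgam 2.62 and Lyz2 2.29; DESeq2 called 11 of the list over all genes. The score was 3.0 in knockout 2 and 1.35 and 0.64 in knockout 1 and 3, with wild type between -0.16 and 0.17. Inflammatory and secreted signals (camera adjusted p = 4.87e-11; adjusted p = 0.222 with an estimated correlation) passed in 10 of 24 genes when adjusted over the list alone, 5 without wild type 1, 4 without wild type 2 and 3 without wild type 3, wild type 4 or knockout 2. Gpnmb had 2.50, the chemokine gene Cxcl2 4.64 (0.117 ± 0.112 CPM in wild type and 2.88 ± 1.86 in knockout; SD, n = 4 and 3), Lcn2 4.37 and Saa3 5.03, and Spp1 2.74 (SE 1.24, edgeR adjusted p = 0.423). Without both libraries numbered 2, 0 genes of either list passed when adjusted over the list alone, though 30 cell cycle genes did.

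Mesenchymal transition and invasion genes were higher in 18 of 25 (median 0.95, camera adjusted p = 2.86e-06; adjusted p = 0.278 with an estimated correlation). Of these 5 passed when adjusted over the list alone, 8 without wild type 4 or knockout 3 and 0 without wild type 1, wild type 2, wild type 3 or knockout 2. Vim, for vimentin, had 1.24 (edgeR adjusted p = 0.210, DESeq2 0.0243), and the matrix protease genes Mmp3 and Mmp9 3.72 and 1.49. Endothelial markers were higher in 15 of 15 genes (median 1.15, camera adjusted p = 3.89e-08; adjusted p = 0.278 with an estimated correlation). Fibroblast and matrix genes were higher in 18 of 20 (median 1.15, camera adjusted p = 3.89e-08; adjusted p = 0.301 with an estimated correlation), such as Lum (1.73) and Thy1 (0.94). Of them 2 passed when adjusted over the list alone, 3 without wild type 3, 13 without knockout 3 and 1 without wild type 1, knockout 1 or knockout 2. Markers of B and plasma cells were higher in 11 of 12 (median 0.86, camera adjusted p = 0.00642; 0.0605 without both libraries numbered 2; adjusted p = 0.222 with an estimated correlation). Those of T and NK cells were higher in 15 of 17 (median 0.29, camera adjusted p = 0.0199; 0.143 without wild type 1 and 0.0749 without knockout 3; adjusted p = 0.502 with an estimated correlation). Prostate basal genes had a median of 0.57 (0.00617; 0.0505 without knockout 1; adjusted p = 0.367 with an estimated correlation). NRF2 targets had one of 0.69 (0.00642; 0.143 without wild type 1 and 0.462 without knockout 1; adjusted p = 0.521 with an estimated correlation), with Hmox1 at 3.47 and Nfe2l2 at 0.93 (edgeR adjusted p = 0.235).

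Other tumour lists did not pass: lipolysis (median 0.14, adjusted p = 0.354), mature adipocyte (-0.19, 0.274; 0.00214 without knockout 2 and 0.00575 without both libraries numbered 2), autophagy and lysosome (-0.01, 0.274; 0.0251 without wild type 3), amino acid response (-0.14, 0.310), glycolysis (-0.12, 0.845), mesothelium (0.22, 0.0934; 0.00160 without knockout 3), muscle (0.07, 0.676) and prostate luminal (-0.32, 0.576). The lipolysis list had a median above and a mean below 0 (-0.13), as did muscle (-0.23), and autophagy the reverse (0.13). Interferon response had 0.11 (0.195, and 0.0380 with the replicate block; 0.0132, 0.0389 and 0.0121 without wild type 2, knockout 1 and knockout 3) and the neuroendocrine list -3.10 (0.212, and 0.0283 with the replicate block; 0.0268 without wild type 2). In list scores the neuroendocrine direction rests on wild type 1, at 3.98 against -1.76 to -0.67 in the other tumours. The erythroid list had 4 measured genes, at a median of 1.74, and was not tested. Epididymis and seminal vesicle genes had a median of 4.05 (0.676) set by knockout 1, where Svs4, a seminal vesicle secretory protein, reached 27525 CPM. Among the genes of smallest p, Chil3, a gene of alternatively activated macrophages, stood at 0.251 ± 0.112 CPM in wild type and 13.8 ± 7.78 in knockout (5.74, edgeR adjusted p = 0.193, DESeq2 1.56e-14). The complement genes C1s1 and C1ra had 1.86 and 1.69, Klf10 1.71 and Nmur2 2.91. Adipocyte genes in the tumours varied widely, with Fabp4 at -0.03, Adipoq at 0.31 and Lep at -1.58, and Cd44 had 0.86, Pparg 0.79, Pnpla2 0.57 and Ppargc1a -0.81; none passed edgeR.

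**Figure D3:**
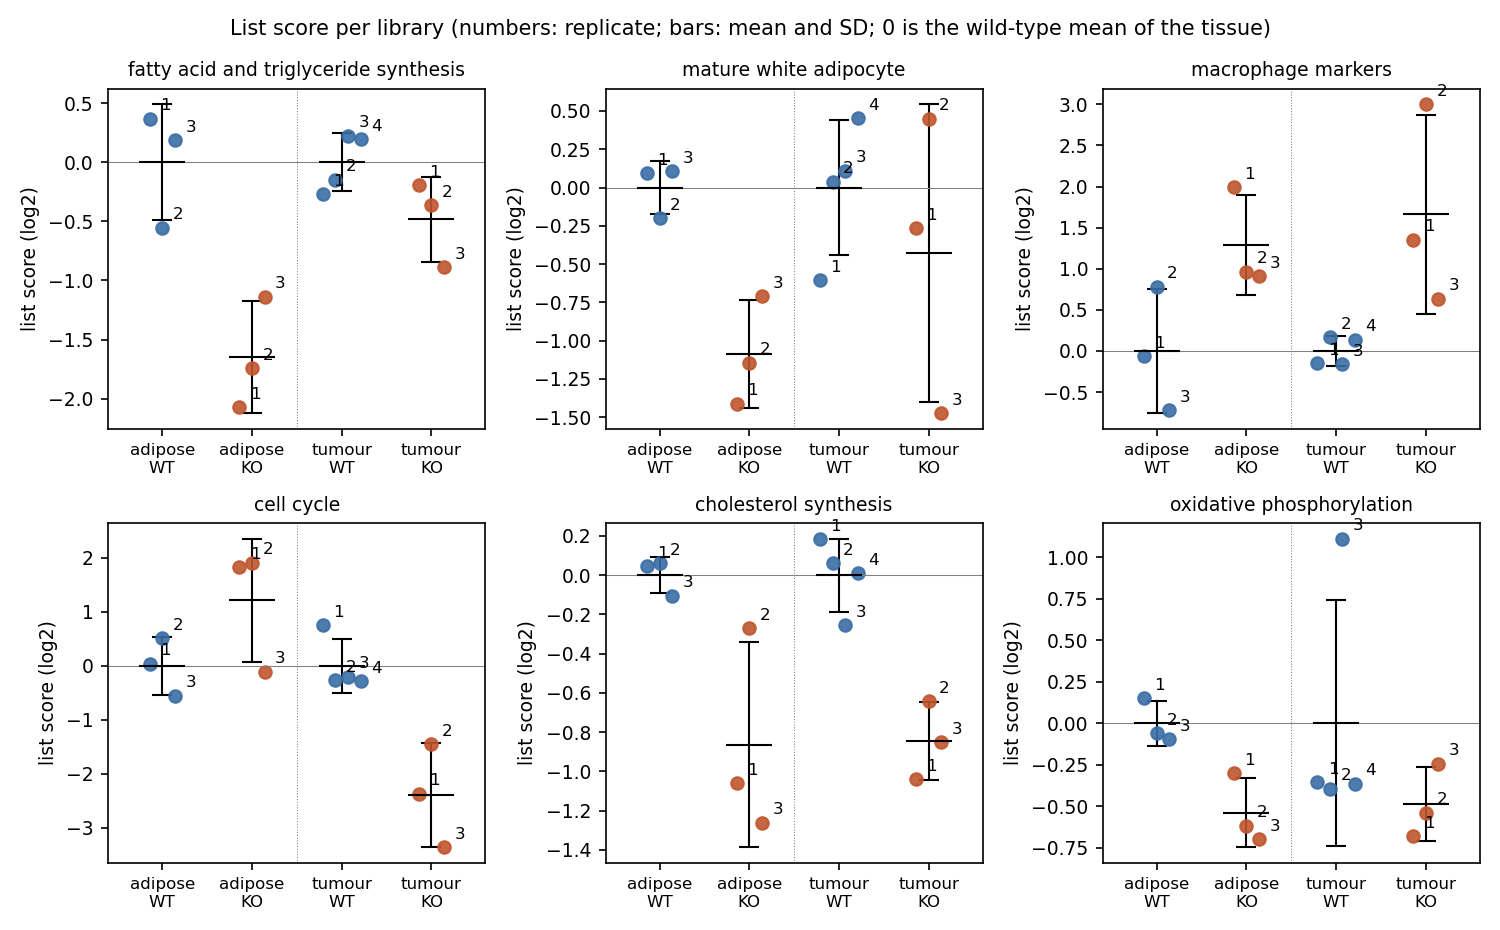
Scores of 6 gene lists in each library, as the mean log2 difference from the wild-type libraries of the same tissue; each point is 1 library with its replicate number, and WT and KO are the labels wild type and knockout. In tumours the cell cycle scores of knockout 1 to 3 (-2.37, -1.45 and -3.36) all lie below those of wild type, and in adipose tissue knockout 3 (-0.11) lies among the wild-type libraries.

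Cell cycle genes differed most between the tissues: the effect in fat minus the effect in tumours had a median of 3.59 over 29 genes, from 1.22 in fat and -2.35 in tumours. In fat alone 0 of the 29 passed when adjusted over the list alone, and the score of knockout 3 (-0.11) lay within the wild-type range of -0.55 to 0.51 (exact permutation p = 0.3). With an estimated correlation the difference was lost (adjusted p = 0.239). Lipid synthesis genes were lower in both tissues and more so in fat (-1.75 against -0.24, difference -1.51), a difference also lost with an estimated correlation (adjusted p = 0.239). Macrophage markers were higher in both (1.34 and 1.48), with no difference that passed (adjusted p = 0.363), but without the 4 libraries numbered 2 the difference turned from lower to higher in fat and passed (0.00868).

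The cell cycle difference gave camera adjusted p = 3.51e-35 (adjusted p = 0.239 with an estimated correlation), with 29 of 29 genes passing when adjusted over the list alone. Mki67 differed by 4.99 (SE 1.26, limma adjusted p = 0.0978) and Nusap1 by 3.92 (0.0547). The lipid synthesis difference gave adjusted p = 2.68e-09 (adjusted p = 0.239 with an estimated correlation), with 9 genes passing when adjusted over the list alone and 16 without adipose knockout 3. Fasn differed by -3.002 (SE 0.80, limma adjusted p = 0.117), Me1 by -3.03 (0.0767), Scd2 by -2.64 (0.0706), Cpt1a by -0.52 (0.758) and Spp1 by 1.20 (0.856). Of 26 lists 9 passed camera, 2 higher and 7 lower in fat relative to tumour, and 0 with an estimated correlation, where the other 7 had adjusted p = 0.610. Those were the TCA cycle (-0.42), fatty acid oxidation (-0.61), mature adipocyte (-0.80; adjusted p = 0.101 without tumour knockout 2), endothelial (-0.84; 0.121 without the 4 libraries numbered 2), fibroblast (-1.35), NRF2 (-0.43; 0.0784 without tumour wild type 1 and 0.243 without tumour knockout 1) and neuroendocrine lists (2.04; 0.0846 without adipose knockout 2 and 0.113 without tumour wild type 1). Macrophage genes differed by -0.34 (0.363; 0.0425 without adipose wild type 3 and 0.00802 without tumour knockout 3), oxidative phosphorylation by 0.01 (0.690; 2.43e-05 without tumour wild type 3) and cholesterol synthesis by 0.08 (0.976). Without the 4 libraries numbered 2 the autophagy, mesothelial, muscle and prostate basal lists also passed (0.00898, 0.0440, 4.51e-04 and 0.0112).

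Of 12390 genes tested in both tissues, limma called 0 for the difference (smallest adjusted p = 0.0547), with 1452 at an unadjusted p under 0.05 (718 higher and 734 lower; 620 expected by chance) and 950 without the 4 libraries numbered 2. Limma called 63 with the replicate block, 221 without adipose knockout 3, 34 without tumour knockout 2, and 1 without adipose wild type 1 or without adipose knockout 1. Across genes, the fold changes of the tissues had a Pearson r of 0.09 and a Spearman rho of 0.10, and 57 and 42 of 100 random relabellings within each tissue gave values as far from 0; genes are not independent replicates. No gene was called in both tissues, with 0 called in tumours by edgeR, so the overlap of calls could not be tested.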

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

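The tests of exchanged labels, cell mixture, other splits and the use of single left-out libraries to weigh an explanation were chosen only after the results were seen; the camera tests of the tissue difference were planned. Within the 4 wild-type tumours, a gene or list was singled out when 1 library lay so far from the rest that the gap to its neighbour took up a large share of the whole range (a Dixon test at p under 0.05). Of 56 genes and 28 lists looked at, 11 were singled out, where 4.2, about 1 in 20, would be by chance were they independent. Some of the genes, such as Mki67 and Nusap1, belong to those lists, and gene values were CPM without a log. The 4.2 is therefore only a rough guide. For genes, wild type 2 was farthest for Sqstm1 (gap over range 0.871), wild type 1 for Spp1 (0.929), Mki67 (0.856), Nusap1 (0.886) and Cd14 (0.839), and wild type 3 for Cxcl2 (0.848). For list scores the gap was 0.921 for cell cycle and 0.866 for neuroendocrine genes, both with wild type 1 farthest, 0.974 for oxidative phosphorylation and 0.873 for the TCA cycle, both with wild type 3, and 0.854 for prostate basal genes, with wild type 2.

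The tissues differed by camera in 9 lists, as the median of the effect in fat minus the effect in tumours. These were cell cycle (3.59), neuroendocrine (2.04), fatty acid and triglyceride synthesis (-1.51), fibroblast and matrix (-1.35), endothelial (-0.84), mature white adipocyte (-0.80), fatty acid oxidation (-0.61), NRF2 (-0.43) and TCA cycle (-0.42). Of the 26 lists tested, these passed at an adjusted p under 0.05 with the preset correlation, and 0 passed with an estimated one.

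Sqstm1 ran against the labels in the libraries numbered 2 of both tissues, and an exchange of the labels of those libraries was weighed first. Tried first, a score over the 200 genes that best part the other libraries put knockout 2 beyond wild type 2, as labelled. The gap was 0.29 in adipose tissue (83.5% of genes) and 0.41 in tumours (98% of genes). Leaving out number 1 or number 3 instead gave gaps of 0.67 and 0.29 in adipose tissue and 0.81 and 0.76 in tumours. Libraries of 1 group lay up to 0.38 and 0.52 apart, but these distances mix the left-out library with libraries that chose the genes. The score therefore did not decide alone. With the labels exchanged, 457 adipose genes had p under 0.05, against 2045 as labelled, and 322 tumour genes, against 1879 as labelled. In tumours DESeq2 called 1 gene with labels exchanged and 780 as labelled, and no other of the 35 splits gave as many genes as the labels. This goes against an exchange of 2 libraries. Only 8 of those splits keep the pairs assumed from replicate numbers, however, too few to rule it out. In adipose tissue it is left open, because another split of the 6 libraries gave 2117 genes, so the number cannot tell the groups apart. That split set wild type 1, wild type 3 and knockout 3 against the rest. It put wild type 2, lowest in Sqstm1, with knockout 1 and 2, but parted knockout 3, also low in Sqstm1, from them. Incomplete deletion in knockout 2 was not tested. It would leave the low Sqstm1 of wild type 2 unexplained, as that library was to keep the gene.

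Lower lipid synthesis and higher macrophage genes in fat could come from fewer adipocytes in the tissue. A lower share of adipocytes alone would raise all other cell types alike. Their 7 list medians spread over 1.57, more than when genes were shuffled among these lists (p = 0.0254 by permutation of genes). Genes are not independent replicates, and those of 1 list tended to move together. The estimated correlation was 0.53 for macrophage, 0.61 for T and NK cell and -0.06 for B cell markers. That can widen the spread by itself, so the test does not decide against fewer adipocytes. A first version with 4 of the 7 lists had given a smaller p. Adipocyte and lipid synthesis genes would also be lowered alike, but the lipid synthesis median was lower still (difference -0.68, p = 0.0251 by permutation of genes). Their estimated correlations were 0.17 and 0.31, so this p has the same limit. The lipid synthesis median was -1.56 without knockout 2, the deepest library by the steps of low values. A changed share of adipocytes may still add to the lower median.

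Lower cell cycle and higher macrophage genes in tumours could likewise come from fewer epithelial cells. A lower epithelial share alone would raise the other cell types alike, and their 7 list medians spread over 1.86 (p = 2.0e-04 by permutation of genes). Genes of 1 list tended to move together here too (estimated correlation 0.67 for macrophage and -0.004 for B cell markers). The spread therefore does not decide. Wild type 1, with neuroendocrine genes, was not the source, as the cell cycle median was -2.07 without it, nor was seminal vesicle RNA in knockout 1, with a median of -2.43 without that library. A shift in the mix of cells could still be part of the pattern, since macrophage, endothelial and fibroblast genes were all higher.

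Regrouping the libraries showed how much any split gives. In adipose tissue, with 10 splits, the share can never be under 0.1: 6 of 10 splits called at least the 1 gene called with the labels (highest other 7), 2 of 10 had as many genes as the 2045 at p under 0.05 (highest other 2117) and 2 of 10 as many as the 15 lists (highest other 17). In tumours, over all splits alike, 1 of 35 had as many as the 1879 genes at p under 0.05 (highest other 1709) and 1 of 35 as many as the 780 DESeq2 calls (highest other 183). If replicate numbers pair the tumours, as assumed here, only 8 splits part every pair as the labels do (highest other 1709 and 140). These are too few for a share under 0.05. The other splits put same-numbered tumours on 1 side or set tumour 4 among the 3. Chance cannot be excluded for the 15 lists (13 of 35, highest other 18). The 0 edgeR calls are met by 35 of 35 splits by construction (highest other 1), which tests nothing. For the tissue difference, 3 of 100 draws had as many as the 1452 genes at p under 0.05 (highest other 1894). The draws ignore the pairs assumed for tumours and any mice shared between tissues, so this does not exclude chance. Nor can chance be excluded for the 9 lists (73 of 100, highest other 20), and the 0 calls are met by 100 of 100 draws by construction (highest other 61). Camera with its preset correlation called at least 4 lists in every adipose split, 6 in every tumour split and 3 in every draw for the tissue difference, so the number of lists says little about genotype.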

How the results depend on the processing

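Of the tests here, those without the libraries numbered 2, without genes under 300 bases and with separate errors for the tissues were chosen only after the results were seen. The others were fixed before. In adipose tissue limma called 1 gene, 20 with a stricter filter, 48 with all 13 libraries in 1 fit, 2 to 4 when 1 library was left out (2 without wild type 3, 4 without knockout 1), 5 without both libraries numbered 2 and 0 without genes under 300 bases, where Snord61 is absent. Of the 15 adipose lists called by camera 0 were called with an estimated correlation and 0 by fry, and 13 to 19 when 1 library was left out. The replicate block, which the pairing check did not call for in adipose tissue, added the mesenchymal list (adjusted p from 0.0670 to 0.0241) and the erythroid list (from 0.0670 to 0.0286).

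In tumours edgeR called 0 genes, DESeq2 780 and the fit of all 13 libraries 4. Of 15 lists 0 were called with an estimated correlation, 1 by fry and 13 to 16 when 1 library was left out. The epididymis and seminal vesicle list turned from higher to lower without knockout 1 (adjusted p = 0.0013; range over its alternatives 0.0013 to 0.905), and its p was 0.896 without knockout 3; the cause was not tested.

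The log2 fold change of Sqstm1 in adipose tissue ran from -2.95 without wild type 2 to -0.48 without wild type 3, and was -4.16 without both libraries numbered 2 (limma adjusted p = 0.0608). In tumours it ran from -3.12 without knockout 2 to -0.34 without knockout 1, and was -3.52 without both libraries numbered 2 (edgeR adjusted p = 0.369).

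For the tissue difference limma called 0 genes, 198 at an adjusted p under 0.10, 63 with a replicate block, 147 with separate errors for the tissues and between 0 (without adipose wild type 2, for example) and 221 (without adipose knockout 3) when 1 library was left out. Of 9 lists 0 were called with an estimated correlation, and 8 to 13 when 1 library was left out. Macrophage genes turned from lower to higher in fat relative to tumour without the 4 libraries numbered 2 (adjusted p = 0.00868; range over its alternatives 0.00802 to 0.931). The endothelial difference was lost there (adjusted p = 0.121). A DESeq2 interaction and DESeq2 on adipose values were not run, as the adipose values are not counts. The value of 1 added to FPKM and CPM in the fit of the tissue difference was not varied, nor was the prior count of the tumour log2 CPM.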

Other observations

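Of the tests named here, the one with exchanged labels was chosen only after the results were seen. Single tumours carried RNA of particular cell states. In the tumour labelled wild type 1 neuroendocrine genes were high, and with them the fold changes of Mycn, an oncogenic transcription factor (-5.47), Insm1, a neuroendocrine regulator (-6.91), and Celf3 (-6.72) were strongly negative without passing edgeR. In the tumour labelled knockout 1, seminal vesicle genes Svs4 (7.81), Svs3a (6.64) and Svs6 (5.46) were high, and Svs4 alone took up 2.71% of its counts.

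Among the lipolysis and lipid droplet genes of fat, 16 were lower and 5 higher in knockout. Plin2, which coats lipid droplets, was 1 of the higher ones and stood at 142 FPKM in wild type and 635 in knockout (log2 fold change 2.06, limma adjusted p = 0.209). Atp6v0d2, a proton pump subunit of macrophages, had 3.53 without passing over all genes.

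Sqstm1 itself leaves the libraries numbered 2 unexplained in both tissues. In fat, 457 genes at p under 0.05 with exchanged labels could not settle the matter. In tumours, the splits went against an exchange without ruling it out. They do not explain the Sqstm1 counts of 135 in wild type 2 and 6053 in knockout 2. Nor do they explain the low counts in knockout 1 and 3 (178 and 461), where no loss was designed. Tumour changes therefore cannot be assigned to adipocyte p62 alone. Genotyping of the remaining tissue, or reads over the floxed exons, could settle whether labels were exchanged. Reads were not analysed here.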
